A study of Mus musculus with 5 samples.

How the data were processed

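Cells of NG2creER:R26tdTomato mouse hearts, sorted as Tomato-positive, CD31-negative and CD45-negative, were captured with the 10x Genomics 3' v3.1 chemistry, per the labels. The study comprised 2 control libraries and 3 libraries taken 7 days after infarction, and the labels give 2 pooled hearts for each except infarct replicate 3, which held 1. The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.1 on the mm10 build, per the submitters' processing notes. The values are whole counts of at least 1 over 32285 genes, the same in all 5 libraries, and the deposited files are named as the tool's filtered matrices. The notes do not state the gene annotation or whether intronic reads were counted, and the feature lists hold no tdTomato or Cre sequence, so lineage label could not be read from the counts. Other data of the study were not used here.

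Cells with at least 500 genes, at least 1000 UMIs and under 15% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as built into scanpy 1.11.5 and removed. Its automatic threshold was used in control replicate 1; in the other libraries it marked under 0.5% of cells, and the highest-scoring 0.8% per 1000 barcodes were removed instead, as fixed beforehand. Doublet calls took 2.6%, 2.34%, 11.5%, 7.06% and 7.24% of cells in control replicates 1 and 2 and infarct replicates 1 to 3. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at a resolution of 1 followed, on all libraries together without integration. Clusters were named from 12 fixed marker lists by their mean log2 fold over the other clusters (a prior of 10 CPM, a score of at least 2, or at least 1 for fibroblast markers, at least 3 markers detected, and a gap of 1 to a rival class), and clusters that met no rule were left unnamed. In the other filters and clusterings each cluster took the name of that cluster of the first clustering whose marker profile correlated best with its own, so a joint cluster carries 1 name whatever its own score. The suffix -like marks that names rest on RNA alone. Share intervals in the tables are 95% Wilson intervals and, like floors, cover counting error only.

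Counts were summed per library over the cells of a class. The sums held 63612 and 171165 UMIs for pericyte-like cells of the controls and 1583512, 2199740 and 2496138 for those of the infarct libraries, so a control gene with 0 counts is only bounded. Floors are 3 counts over the group. For fibroblast-like cells the sums ran from 11661223 to 215838269 UMIs, and for smooth muscle-like cells from 602513 to 2958537. Genes were filtered with filterByExpr, normalised with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with group as the single term. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. CPM values of the gene tests use TMM library sizes. Raw CPM values are given with the interaction tests, for single genes of the smooth muscle-like clusters and for Xist and Ddx3y. They are also given for Cspg4 compared across classes and in the tests of technical explanations. Differences in response between classes were tested as an interaction on the sums of both classes with the library as a block. The 20 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 among lists with at least 4 tested members. Members were also adjusted over the list alone. Shares were compared with a two-sided exact permutation test and with edgeR on cell numbers.

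These tests, the marker and gene lists, the rule for named genes and a set of other settings were fixed before the data were examined. Named genes were the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted, mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes. To these came up to 4 members with the lowest p of each list that passed and of the pericyte identity, contractile and collagen lists, 14 marker genes named in any case, and 5 genes per direction for each interaction. The other settings fixed then were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, no filter on low counts, a replicate block, leaving out each library, camera with an estimated correlation and fry. They also included stricter (1000 genes, 2000 UMIs, 10%) and looser (200 genes, 500 UMIs, 25%) cell filters, doublets kept, Leiden resolutions of 0.5 and 2, clustering without list genes, 824 cells drawn from each library, and shares among 3 classes. Chosen after seeing the data were a minimum of 5 instead of 20 cells per library for pericyte-like cells, tests of glial-like cells and of 1 fibroblast-like cluster, the interaction of smooth muscle-like and fibroblast-like cells, tests without 1 fibroblast-like or 1 smooth muscle-like cluster, and a term for pools with female hearts. The glial-like test also kept a library under 20 cells, infarct replicate 3 with 15. The intervals for the collagen list in pericyte-like cells, also chosen then, came from 2000 draws of cells with replacement within each library.

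The tests were run on simulated data with the real means and library sizes. Of genes changed 2-fold and 4-fold, the fibroblast-like test (20492 genes) recovered 36.1% and 69.9%, the smooth muscle-like test (10831 genes) 18.3% and 80.2%, the test over all cells (20774 genes) 29.2% and 74.8%, and the pericyte-like test (10891 genes) 0% and 37.3%, with 3, 5, 1 and 3 false calls. The interaction tests recovered 20% (smooth muscle-like against pericyte-like), 27.5% (fibroblast-like against pericyte-like) and 76% (smooth muscle-like against fibroblast-like) of genes changed 4-fold, with 0, 0 and 6 false calls. Gene positions came from GENCODE vM21 on GRCm38. Clustering and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.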

Results

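Single-cell RNA libraries were made from hearts of NG2creER:R26tdTomato mice, in which tamoxifen switches on the red fluorescent protein tdTomato in cells that express NG2 (the product of Cspg4) and in their descendants. Cells with Tomato signal and without the endothelial marker CD31 or the leukocyte marker CD45 were sorted, and every share given here describes that sorted fraction and not the heart. There were 2 control libraries without surgery, from 4 hearts, and 3 libraries taken 7 days after infarction, from 5 hearts. Each library but infarct replicate 3, which came from 1 heart, pooled 2 hearts, so the library and not the heart or the cell was the replicate. The deposited matrices held 15474250 and 36443694 UMIs over 1022 and 2936 barcodes in control replicates 1 and 2. They held 277295944, 230341664 and 185831706 UMIs over 14134, 9030 and 9198 barcodes in infarct replicates 1 to 3. After filtering, 824 and 2295 control cells and 11614, 7455 and 7157 infarct cells remained, with medians of 16318, 14337, 18578, 24505 and 19370 UMIs per cell in that order.

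The first question was which cell types the NG2 lineage fraction held and whether their shares differed after infarction. Most cells carried fibroblast markers such as Pdgfra, Dcn and Gsn in every library, and these fibroblast-like cells made up 71.4% and 84.4% of the control libraries and 88.3%, 86.6% and 90.4% of the infarct libraries. Cells with the mural markers Rgs5, Kcnj8, Abcc9 and Vtn, called pericyte-like, made up 0.965% ± 0.0087 (SD, n = 2) of control cells and 1.58% ± 0.43 (SD, n = 3) of infarct cells. Cells with Myh11, Acta2 and Tagln, called smooth muscle-like, made up 13.5% ± 9.1 (SD, n = 2) and 1.35% ± 0.62 (SD, n = 3). Glial-like cells, with Sox10 among their markers, made up 5.46% and 3.22% of control libraries and 0.233%, 0.738% and 0.210% of infarct libraries.

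The smooth muscle-like mean share was lower by 12.1 percentage points after infarction (difference -12.1), the fibroblast-like mean was 10.6 points higher, and the pericyte-like mean was 0.612 points higher. In each of these 3 classes the libraries of the 2 groups did not overlap, but the pericyte-like shares did overlap with the stricter filter, the looser filter and equal cells (exact permutation p = 0.6, 0.4 and 0.6), and the difference with the looser filter was 0.322 points. For the 3 classes the two-sided exact permutation test gave p = 0.2, the smallest that the 10 splits of 5 libraries allow, so the design could not reach 0.05. Control replicate 1 set much of the size: without it the smooth muscle-like difference was -5.67 points and the fibroblast-like difference 4.09 points. Without control replicate 2 they were -18.6 and 17.1 points. The edgeR test on cell numbers gave a log2 fold change of -3.30 for smooth muscle-like cells (adjusted p = 0.00977), lower in all 3 infarct libraries than in both controls. It gave -3.45 for glial-like cells (adjusted p = 0.00977), 2.05 for mesothelial-like cells and 1.248 for unnamed cells (adjusted p = 0.0442 in both), 0.71 for pericyte-like cells (adjusted p = 0.172) and 0.18 for fibroblast-like cells (adjusted p = 0.522). At a Leiden resolution of 0.5 the pericyte-like cells joined the smooth muscle-like cells, and the difference for that joint class was -10.3 points.

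**Figure D1:**
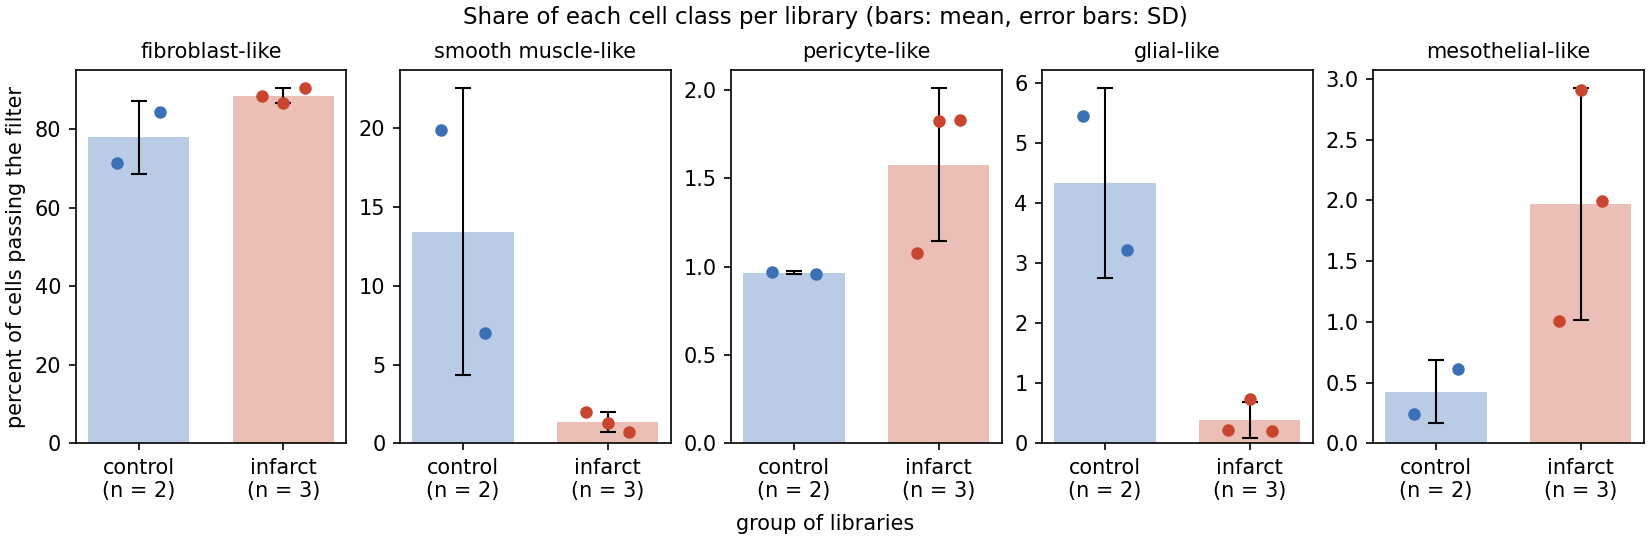
Share of each cell class (percent of cells passing the filter) in 2 control and 3 infarct libraries; bars are means, error bars SDs and points libraries. Smooth muscle-like cells made up 19.9% and 7.02% of the control libraries and no more than 1.99% of an infarct library.

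The second question was how fibroblast-like cells differed after infarction. Cthrc1, a secreted regulator of collagen deposition, rose from 20.1 ± 5.3 CPM (SD, n = 2) to 1134 ± 256 CPM (SD, n = 3), a log2 fold change of 5.83 (SE 0.33, adjusted p = 9.3e-04). Col1a1, which encodes the main chain of type I collagen, rose from 981 ± 92.5 to 6941 ± 1796 CPM (log2 fold change 2.82, SE 0.30, adjusted p = 0.00348). Fn1, which encodes fibronectin, rose from 156 ± 45.7 to 2724 ± 494 CPM (4.12, SE 0.30, adjusted p = 0.00149). Gsn, which encodes an actin-severing protein, fell from 15430 ± 1764 to 2369 ± 286 CPM (-2.70, SE 0.21, adjusted p = 0.00167). The small proteoglycan gene Dcn fell from 14600 ± 1369 to 6855 ± 135 CPM (-1.09, SE 0.19, adjusted p = 0.0146). Of 20492 genes tested with edgeR, 1741 rose and 1638 fell.

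Other genes with large rises were Kif26b (3.25 to 363 CPM), an unconventional kinesin, Cemip (0.965 to 76.8 CPM), which degrades hyaluronan, Lox (27.3 to 641 CPM), which crosslinks collagen, and Tnc (7.36 to 307 CPM), a matricellular protein. The contractile gene Acta2 rose from 106 ± 0.57 to 455 ± 228 CPM (log2 fold change 2.10, SE 0.40, adjusted p = 0.0179), Postn from 1434 ± 376 to 3688 ± 1268 CPM (1.36, SE 0.36, adjusted p = 0.0457) and the proliferation marker Mki67 from 1.93 ± 1.1 to 43.0 ± 29.3 CPM (4.34, SE 0.74, adjusted p = 0.013). Infarct replicate 3 stood highest in both Acta2 (353, 295 and 716 CPM in infarct replicates 1 to 3) and Mki67 (35.3, 18.2 and 75.4 CPM), and it held 1091 of 1194 and 965 of 1094 cells of 2 clusters high in both genes. Tgfb1 was at 76.5 ± 21.7 and 74.1 ± 21.4 CPM (adjusted p = 0.932), and Cspg4 at 12.7 ± 3.7 and 17.4 ± 8.0 CPM (adjusted p = 0.475). Erbb4, Cytl1, Chad and Wif1, an inhibitor of Wnt proteins, were among the 8 largest falls. These 4 genes marked 1 cluster that held 31.1% and 37.9% of control and 8.55%, 4.46% and 7.96% of infarct fibroblast-like cells. Without that cluster, a setting chosen after seeing the data, the log2 fold change of Wif1 was 0.25. The classes were not made of the same clusters in both groups. The clusters numbered 1, 3 and 6 held 98.0% and 95.9% of control fibroblast-like cells and 18.8%, 20.4% and 28.7% of infarct ones. The count of 3379 changed genes was 730 without control replicate 1, 218 without control replicate 2 and 1493 without infarct replicate 2.

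**Figure D2:**
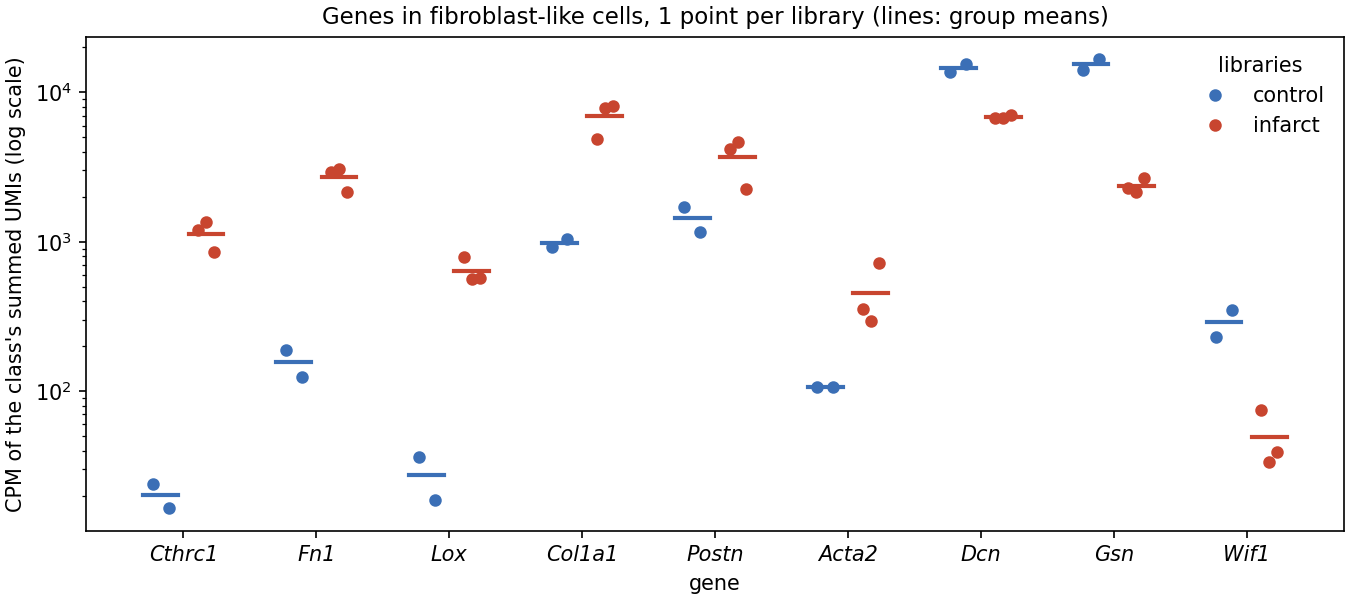
CPM (log axis) of 9 genes in fibroblast-like cells, with 1 point per library and lines at group means. Cthrc1, Fn1, Lox, Col1a1, Postn and Acta2 were higher and Dcn, Gsn and Wif1 lower in all 3 infarct libraries than in both controls.

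Of the 20 gene lists, 9 passed camera in fibroblast-like cells, and none passed with an estimated correlation. Of the 21 interstitial collagen and elastic fibre genes, 16 rose (17 rose and 1 fell when adjusted over the list alone) with a median log2 fold change of 1.45, among them Col11a1, Col5a1 and Col5a2 (adjusted p = 2.0e-22, and adjusted p = 0.051 with an estimated correlation). In collagen processing and crosslinking 11 of 16 rose (13 rose and 1 fell adjusted over the list alone), with P4ha3 and Loxl3 among them (adjusted p = 1.9e-12, and adjusted p = 0.161 with an estimated correlation). In the cell cycle list 21 of 30 rose (24 adjusted over the list alone; adjusted p = 4.8e-17, and adjusted p = 0.522 with an estimated correlation). In the contractile apparatus 9 of 16 rose and 2 fell (10 and 2 adjusted over the list alone), with Tagln, Cnn1 and Myl9 among those that rose (adjusted p = 2.8e-05, and adjusted p = 0.161 with an estimated correlation). Matricellular proteins had 6 of 14 that rose and 1 that fell (7 and 1 adjusted over the list alone; adjusted p = 9.9e-08, and adjusted p = 0.161 with an estimated correlation).

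Among matrix proteases and inhibitors 7 of 21 rose and 1 fell (10 and 2 adjusted over the list alone), with Mmp14 and Adam12 among those that rose (adjusted p = 0.00511, and adjusted p = 0.203 with an estimated correlation). Among chemokines, cytokines and adhesion genes 3 of 17 rose (5 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.70 with an estimated correlation). Cytosolic ribosomal protein genes had a median log2 fold change of 0.29, and 3 of 79 rose (0 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.70 with an estimated correlation). The immediate early and dissociation stress list went down: 10 of 22 fell and 1 rose (13 and 1 adjusted over the list alone), with Junb (1237 to 702 CPM) and Egr1 (1108 to 642 CPM) among those that fell (adjusted p = 0.0013, and adjusted p = 0.70 with an estimated correlation). The lists for basement membrane, small leucine-rich proteoglycans, pericyte identity, integrins, TGF-beta signalling, PDGF, Notch and angiopoietin signalling, interferon response and antigen presentation, complement, oxidative phosphorylation, glycolysis and hypoxia, and chondro-osteogenic genes did not pass.

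The third question was how the pericyte-like cells differed. The controls held only 8 and 22 such cells, under the planned minimum of 20 cells in control replicate 1, so this test used a minimum of 5 cells chosen after the cells had been counted. Vtn, which encodes vitronectin, fell from 1721 ± 52.1 CPM (SD, n = 2) to 342 ± 117 CPM (SD, n = 3; log2 fold change -2.33, SE 0.32, adjusted p = 0.00482), and Kcnj8, a potassium channel subunit, fell from 1072 ± 248 to 442 ± 24.6 CPM (-1.29, SE 0.26, adjusted p = 0.0342). Ccn3, a matricellular signalling protein, fell from 572 ± 60.1 to 23.3 ± 11.5 CPM (-4.64, SE 0.40, adjusted p = 4.2e-04). Col1a1 rose from 324 ± 3.0 to 1567 ± 381 CPM (2.28, SE 0.33, adjusted p = 0.0073). Serpine2, a protease inhibitor, rose from 290 ± 12.2 to 1199 ± 148 CPM (2.05, SE 0.30, adjusted p = 0.00738). Of 10891 genes tested, 91 rose and 54 fell, while DESeq2 called 299 and limma-voom 76. The edgeR count of 145 was 1 without control replicate 1, 0 without control replicate 2 (1261 at an unadjusted p under 0.05), 377 without infarct replicate 1, 48 without infarct replicate 2 and 235 without infarct replicate 3.

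Mki67, Top2a and the cation channel gene Trpc6 had 0 counts in the control pericyte-like cells and 984, 1014 and 1557 in the infarct ones. Against a floor of 3 counts over the control group they were at least 12.3-fold, 12.6-fold and 19.4-fold higher (adjusted p = 0.0112, 0.00886 and 0.00347). Such floors cover counting error only and not the draw of the 8 and 22 control cells. The protease gene Adam12 had 2 control counts, a ratio of 27.7 with a 95% counting interval of 7.66 to 229 (adjusted p = 0.00886). Rgs5, a regulator of G protein signalling and the most abundant marker of the class, was at 9493 ± 944 CPM in controls and 5156 ± 599 CPM after infarction (log2 fold change -0.88, SE 0.28, adjusted p = 0.145). Pdgfrb was at 1019 ± 289 and 684 ± 107 CPM (adjusted p = 0.32), Cspg4 at 170 ± 67.9 and 130 ± 24.2 CPM (adjusted p = 0.512), and Acta2 at 2324 ± 654 and 4273 ± 1156 CPM (adjusted p = 0.203). Cthrc1 had 0 control and 174 infarct counts, at least 2.17-fold higher (adjusted p = 0.146), and 31.2 ± 13.5 CPM after infarction against 1134 CPM in fibroblast-like cells. Postn was at 665 ± 18.4 and 1111 ± 55.4 CPM (adjusted p = 0.196). The fibroblast marker Dcn was at 452 ± 466 and 614 ± 337 CPM in these cells (adjusted p = 0.812), against 14600 and 6855 CPM in fibroblast-like cells.

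**Figure D3:**
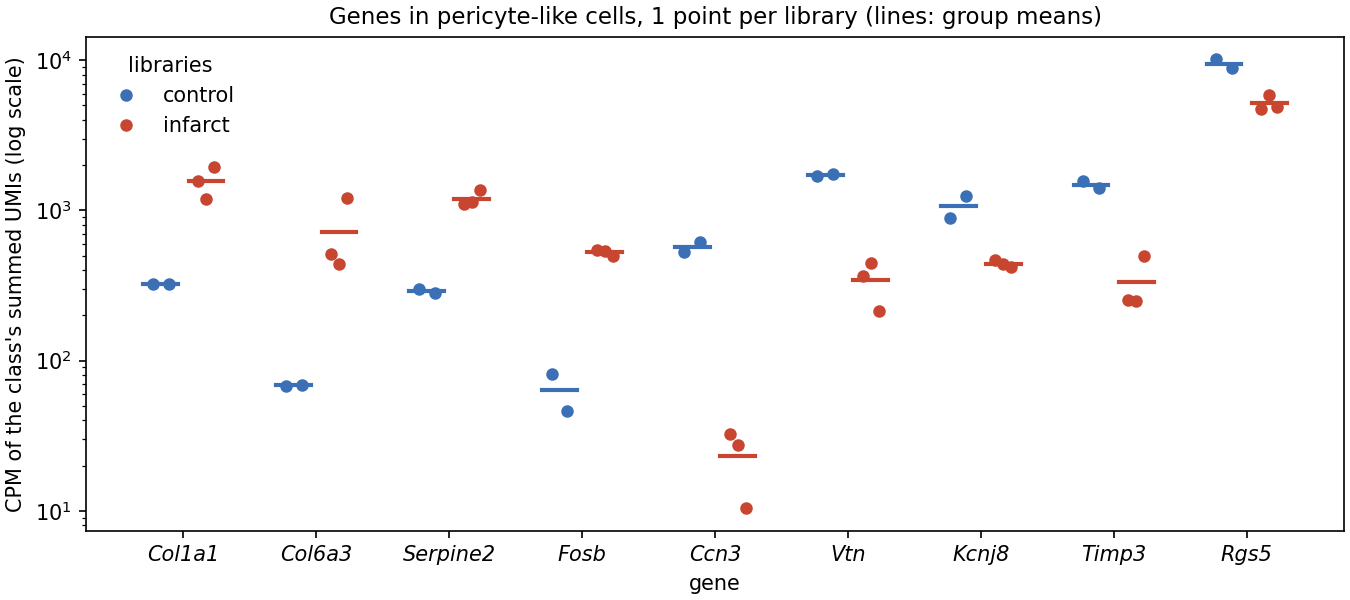
CPM (log axis) of 9 genes in pericyte-like cells, with 1 point per library and lines at group means. The controls rest on 8 and 22 cells; Rgs5 lay lower in all 3 infarct libraries than in both controls but did not pass the threshold (adjusted p = 0.145).

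In pericyte-like cells 13 lists passed camera and none with an estimated correlation. In the pericyte identity list 5 of 18 fell and 0 rose (11 fell adjusted over the list alone), with Vtn, Kcnj8, Abcc9 and Steap4 among them (median -0.81, adjusted p = 3.6e-15, and adjusted p = 0.299 with an estimated correlation). In PDGF, Notch and angiopoietin signalling 3 of 19 fell (3 adjusted over the list alone): Angpt1, a ligand of the endothelial receptor Tek, from 186 to 30.6 CPM, Pdgfd and the Notch target Hes1 (adjusted p = 4.8e-05, and adjusted p = 0.299 with an estimated correlation). Of 20 interstitial collagen and elastic fibre genes 4 rose (11 adjusted over the list alone): Col1a1, Col1a2, Col6a3 and Col15a1 (median 1.18, adjusted p = 2.4e-09, and adjusted p = 0.299 with an estimated correlation). In the cell cycle list 8 of 30 rose (24 adjusted over the list alone; adjusted p = 1.1e-21, and adjusted p = 0.34 with an estimated correlation), with a median log2 fold change of 7.88 as fitted and 1.82 with genes at 0 set to their bound. Among matrix proteases and inhibitors 6 of 19 rose, Serpine2 among them, and Timp3 fell (8 and 2 adjusted over the list alone; median 0.71, and 0.67 at the bound; adjusted p = 1.4e-05, and adjusted p = 0.299 with an estimated correlation).

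Immediate early and dissociation stress genes had 2 of 22 that rose and 1 that fell (8 and 2 adjusted over the list alone), with Fosb at 63.7 and 526 CPM (adjusted p = 3.9e-06, and adjusted p = 0.359 with an estimated correlation). Among chemokines, cytokines and adhesion genes 3 of 13 rose (Ccl2, Cxcl1 and Il1r1) and Cxcl12 fell (5 and 1 adjusted over the list alone; median 4.27 as fitted, 0.99 at the bound; adjusted p = 0.00495, and adjusted p = 0.359 with an estimated correlation). Ribosomal protein genes had 2 of 77 that rose (38 adjusted over the list alone; median 0.75, adjusted p = 7.9e-23, and adjusted p = 0.363 with an estimated correlation). In matricellular proteins 0 of 14 passed (6 rose adjusted over the list alone; median 1.71 as fitted, 0.59 at the bound; adjusted p = 0.00431, and adjusted p = 0.359 with an estimated correlation). Interferon response, oxidative phosphorylation, glycolysis and hypoxia, and chondro-osteogenic genes passed upward with 0 single members past the edgeR threshold over all genes, and their adjusted p with an estimated correlation was 0.391, 0.568, 0.391 and 0.49. Adjusted over the list alone, 1, 1, 1 and 0 of their members rose. Their medians were 0.997, 0.377, 0.61 and 7.65 as fitted and 0.802, 0.377, 0.61 and 0.676 at the bound. Of the 5 chondro-osteogenic members 4 had 0 counts in a group. The lists for basement membrane, collagen processing and crosslinking, small leucine-rich proteoglycans, contractile apparatus, integrins, TGF-beta signalling and complement did not pass.

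**Figure D4:**
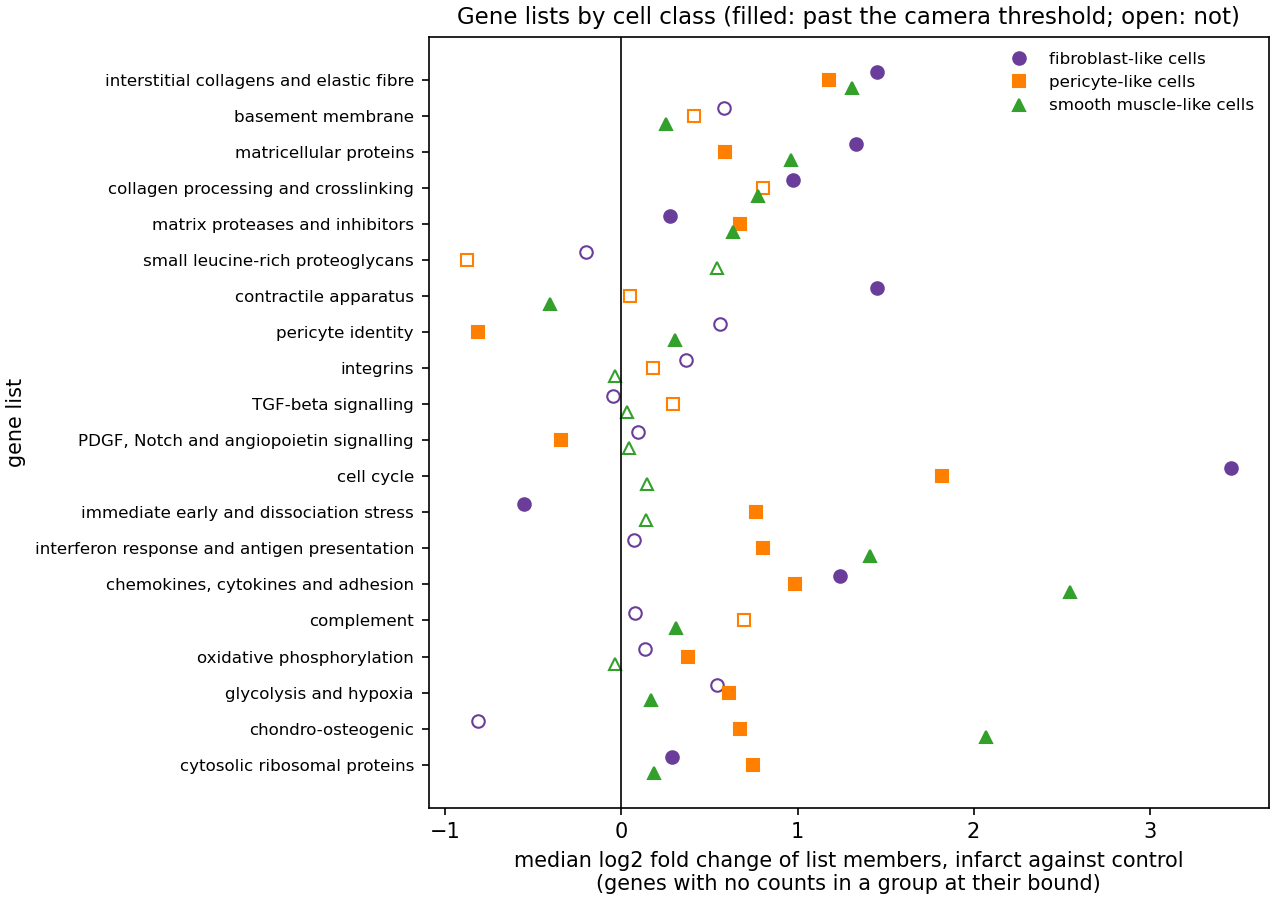
Median log2 fold change (infarct against control) of the members of 20 gene lists in 3 cell classes, with genes at 0 counts in a group placed at their bound; filled symbols passed camera with a preset correlation. Pericyte identity was at -0.81 in pericyte-like cells and 0.30 in smooth muscle-like cells; none of the filled symbols held with an estimated correlation.

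The fourth question was the response of smooth muscle-like cells, which numbered 164 and 161 in controls and 231, 97 and 54 in infarct libraries. The contractile genes Acta2 and Myh11 were at 16510 ± 215 and 6425 ± 1058 CPM in controls (SD, n = 2) and 12230 ± 761 and 4778 ± 722 CPM after infarction (SD, n = 3), with adjusted p = 0.71 and 0.727. Rgs5 was at 1490 ± 168 and 2926 ± 957 CPM (log2 fold change 0.97, SE 0.32, adjusted p = 0.509), and Cspg4 at 245 ± 7.1 and 244 ± 29.5 CPM. The edgeR test called 0 of 10831 genes, with 830 at an unadjusted p under 0.05, while DESeq2 called 70 and limma-voom 0. Without infarct replicate 1 edgeR called 50. The class was made of 2 clusters, and the smaller, led by Itga8 and Sost with Rgs5 at 43.9 against 2575 CPM in the other, held 7 and 44 control and 74, 1 and 0 infarct cells. Without it, a setting chosen after seeing the data, edgeR called 161 genes.

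In smooth muscle-like cells 13 lists passed camera with 0 single genes past the edgeR threshold, and none passed with an estimated correlation. The contractile apparatus went down, with a median log2 fold change of -0.41 over 16 genes (0 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.383 with an estimated correlation). The pericyte identity list went up, with a median of 0.30 over 17 genes (2 rose adjusted over the list alone; adjusted p = 8.7e-04, and adjusted p = 0.383 with an estimated correlation). Interstitial collagens went up as a list, with a positive fold in 20 of 20 members, 0 of which passed singly, and a median of 1.31 (5 rose adjusted over the list alone; adjusted p = 7.9e-13, and adjusted p = 0.383 with an estimated correlation). The fibroblast genes Dpt, at 1.63 ± 1.1 and 30.9 ± 19.6 CPM (adjusted p = 0.218), and Dcn, at 176 ± 87.7 and 386 ± 408 CPM (adjusted p = 0.804), were also higher on average, and fibroblast RNA was not taken out of these sums. Collagen processing, matrix proteases, interferon response, chemokines and chondro-osteogenic genes also went up, with 6, 5, 0, 5 and 4 members that rose when adjusted over the list alone (adjusted p = 0.269 with an estimated correlation in each). Basement membrane, matricellular proteins, complement, glycolysis and hypoxia, and ribosomal protein genes went up with 3, 4, 3, 0 and 0 members that rose and 0, 1, 0, 0 and 0 that fell when adjusted over the list alone. Their adjusted p with an estimated correlation was 0.456, 0.42, 0.412, 0.505 and 0.89. Small leucine-rich proteoglycans, integrins, TGF-beta signalling, PDGF, Notch and angiopoietin signalling, cell cycle, immediate early genes and oxidative phosphorylation did not pass.

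Over all sorted cells together, where differences in make-up and within cells add up, the contractile genes Myh11 (708 ± 525 to 45.73 ± 20.01 CPM, log2 fold change -3.95, SE 0.57, adjusted p = 0.00883) and Lmod1 (138 ± 74.0 to 14.6 ± 6.1 CPM, -3.24, SE 0.43, adjusted p = 0.00731) fell. Cthrc1 rose from 17.01 ± 3.3 to 1069 ± 224 CPM (5.98, SE 0.30, adjusted p = 0.001) and Kif26b from 3.43 ± 0.25 to 368 ± 41.8 CPM (6.75, SE 0.21, adjusted p = 3.3e-04). Rgs5 fell from 246 ± 98.8 to 89.9 ± 10.0 CPM (-1.45, SE 0.25, adjusted p = 0.0134), while Cspg4 was at 41.0 ± 12.5 and 20.2 ± 8.7 CPM (adjusted p = 0.102). Of 20774 genes 1924 rose and 1902 fell, and the count of 3826 was 873 without control replicate 1, 850 without control replicate 2 and 1729 without infarct replicate 2. Of the 11 lists that passed, interstitial collagens (15 of 21 rose, 18 adjusted over the list alone) also passed with an estimated correlation (adjusted p = 0.0447). In the contractile apparatus 10 of 16 fell (15 adjusted over the list alone; adjusted p = 5.2e-12, and adjusted p = 0.395 with an estimated correlation). Matricellular proteins, collagen processing, matrix proteases, cell cycle, interferon response, chemokines and ribosomal protein genes also went up (adjusted p = 0.114, 0.114, 0.395, 0.395, 0.695, 0.695 and 0.75 with an estimated correlation). Of their members 6, 12, 7, 21, 4, 5 and 4 rose (7, 14, 9, 25, 4, 5 and 0 adjusted over the list alone), while 1 matricellular and 2 matrix protease genes fell (adjusted over the list alone, 1 and 3, and 1 in collagen processing). Pericyte identity and immediate early genes went down, with 7 of 18 and 10 of 22 that fell and 0 and 1 that rose (7 and 12 fell and 0 and 2 rose adjusted over the list alone; adjusted p = 0.395 and 0.695 with an estimated correlation).

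The last question was whether the classes differed in their response, tested as an interaction with the library as a block. Between smooth muscle-like and pericyte-like cells 37 of 12025 genes differed. Rgs5 was among them, with a difference of the log2 changes of 1.75 (SE 0.25, adjusted p = 0.0135), from 1483 to 2885 CPM in smooth muscle-like and from 10370 to 4813 CPM in pericyte-like cells before normalisation between libraries. The edgeR count was 0 without control replicate 1 and 0 without control replicate 2 (1130 and 1149 at an unadjusted p under 0.05), 233 without infarct replicate 1 and 110 without infarct replicate 2. Between fibroblast-like and pericyte-like cells 124 of 14665 genes differed. Ccn3 had a difference of 6.59 (SE 0.39, adjusted p = 3.8e-05) and Vtn of 4.21 (SE 0.44, adjusted p = 0.00322). That edgeR count was 45 without control replicate 1, 0 without control replicate 2 (1433 at an unadjusted p under 0.05), and 193, 224 and 299 without infarct replicates 1, 2 and 3.

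By Ensembl gene ID, 32158 of the genes in the files matched the GENCODE vM21 annotation of GRCm38, the assembly of mm10. On it, Cthrc1 (ENSMUSG00000054196) lies on chromosome 15 from 39076932 to 39087121, Vtn (ENSMUSG00000017344) on chromosome 11 from 78499091 to 78502324, Rgs5 (ENSMUSG00000026678) on chromosome 1 from 169655501 to 169695813, and Myh11 (ENSMUSG00000018830) on chromosome 16 from 14194535 to 14291372. All 4 are annotated as protein-coding.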

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

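The interaction of smooth muscle-like with fibroblast-like cells and the tests of technical explanations in this part were chosen only after the results were seen; the other interactions were planned. What drew attention was a tested difference between 2 cell classes in their response to infarction, and 1 cell class outside the comparisons that was more frequent in every infarct library than in the controls.

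The response differed in 37 genes between smooth muscle-like and pericyte-like cells by edgeR. The log2 change after infarction was higher in smooth muscle-like cells by 3.55 for Angpt1, 2.44 for Tshz2, 5.00 for Dpt, 1.75 for Rgs5 and 2.92 for G0s2. It was lower there for Csrp2 (-2.74), H2afz (-2.27), Fosb (-2.43), Hmgb2 (-2.48) and Trpc6 (-10.34). Trpc6 had 0 counts in the control pericyte-like cells, so its fitted difference depends on the prior count and is no bound. Without control replicate 1 or control replicate 2 the edgeR count was 0 (1130 and 1149 genes at an unadjusted p under 0.05), and without infarct replicates 1 and 2 it was 233 and 110.

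The response differed in 124 genes between fibroblast-like and pericyte-like cells. The change was higher in fibroblast-like cells by 6.59 for Ccn3, 2.86 for Prss23, 4.21 for Vtn and 2.48 for Kalrn, on the log2 scale. It was lower there for Fosb (-3.04), Igfbp5 (-3.80), Cxcl1 (-4.26), Trpc6 (-18.11) and Fgl2 (-15.98), and the last 2 had 0 counts in control pericyte-like cells, so their fitted values are no bounds. Cxcl1 had 3 control counts there, a ratio of 36.1 with a 95% counting interval of 12.3 to 175. Without control replicate 1 the edgeR count was 45, without control replicate 2 it was 0 (1433 genes at an unadjusted p under 0.05), and without infarct replicates 1, 2 and 3 it was 193, 224 and 299.

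The response differed in 130 genes between smooth muscle-like and fibroblast-like cells. The change was higher in smooth muscle-like cells by 3.05 for Gsn, 2.79 for Hecw2, 4.07 for Procr, 2.26 for Entpd1 and 2.51 for Cdh13, and lower for Lgi2 (-3.99), Plekho1 (-3.15), Palld (-3.40), Tagln (-2.57) and Kalrn (-2.78). The count was 21 without control replicate 2, and 306, 86 and 19 without infarct replicates 1, 2 and 3. Mesothelial-like cells made up 0.243% and 0.61% of the control libraries and a mean of 1.97% of the infarct libraries (1.01%, 2.91% and 2.00%; edgeR on cell numbers, log2 fold change 2.05, adjusted p = 0.0442). With Leiden resolution 0.5, doublets kept, clustering without list genes or equal cells, the cells with mesothelial markers shared 1 cluster with fibroblast-like cells and took their name. Unnamed cells made up 1.82% and 3.09% of the control and 7.15%, 6.24% and 4.50% of the infarct libraries (edgeR on cell numbers, log2 fold change 1.248, adjusted p = 0.0442). Their shares overlapped between the groups with the stricter filter and with equal cells (exact permutation p = 0.4 in both). The difference of 3.50 points was 1.35 points with the stricter filter. No biological explanation was tested for these differences between classes or for the mesothelial-like share.

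Collagen genes were higher in pericyte-like cells after infarction (median log2 ratio 1.08 over 20 list members), and fibroblast-like cells shared the same droplet runs. The 95% intervals of that median from cells drawn again within libraries stayed above 0 with both controls (0.722 to 1.64). They did so with control replicate 1 (0.493 to 1.80) or 2 (0.551 to 1.36) alone. These intervals draw on 8 and 22 control cells and hold the 2 control libraries fixed, so they do not cover variation between hearts. The bound of 0 replaced one of 1, not met, after the values were seen, so chance from the few control cells is not excluded. With a fibroblast RNA share of 0% to 14.1% per library, estimated from 9 fibroblast genes, taken out, the median was 0.782 with an interval from 0.326 to 1.26. This interval replaced, after the values were seen, a lower quartile above 0 as the criterion, which was not met (-0.775, with 13 of 20 members above 0). Fibroblast RNA is therefore not excluded either, and a member such as Fbln2 could still owe its UMIs to it. For Cthrc1, the level in infarct pericyte-like cells was 0.335 of what that share would bring, so its UMIs there may come from fibroblast RNA and the share may be set too high, while a response of the pericyte-like cells and a change in which of them were sorted stay open, as does the list itself, which did not pass with an estimated correlation (adjusted p = 0.299).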

How the results depend on the processing

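The cause was not tested for any shift given here except where fewer cells, libraries or genes follow from the setting. Counts of changed genes in fibroblast-like and all sorted cells stayed within 1.5 times under both cell filters, kept doublets and other size factors, but limma-voom gave 1853 and 2283. For pericyte-like cells DESeq2 gave 299, limma-voom 76, no filter on low counts 723, the looser cell filter 72 and Leiden resolution 0.5, which joins them with smooth muscle-like cells, 2404. For smooth muscle-like cells DESeq2 gave 70, no filter 207 and kept doublets 5. For the glial-like cells and the Wif1-led cluster, both chosen after seeing the data, no filter gave 636 and 281, and DESeq2 gave 39 for the latter. Also chosen then, a term for pools with female hearts gave 288 for pericyte-like cells, and leaving out the Itga8 and Sost cluster gave 161 for smooth muscle-like cells.

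Leaving out 1 library gave 0 to 377 genes for pericyte-like, 218 to 3713 for fibroblast-like, 0 to 50 for smooth muscle-like, 850 to 3544 for all sorted, and 75 to 381 for glial-like cells and 0 to 3 for the Wif1-led cluster. It gave 0 to 233 for the interaction of smooth muscle-like with pericyte-like, 0 to 299 for fibroblast-like with pericyte-like and 19 to 306 for smooth muscle-like with fibroblast-like cells. Where 1 control was left, edgeR assumed that it varies like the infarct libraries. Interaction counts also moved: smooth muscle-like with pericyte-like to 67 (stricter filter), 18 (looser), 132 (doublets kept) and 82 (clustering without list genes); fibroblast-like with pericyte-like to 60 (looser), 218 (doublets kept), 1624 (Leiden 0.5) and 246 (equal cells); smooth muscle-like with fibroblast-like to 291 (doublets kept).

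Lists past the threshold numbered 13, 9, 13, 11, 7 and 11 in pericyte-like, fibroblast-like, smooth muscle-like, all, glial-like and Wif1-led cells; an estimated correlation left 0, 0, 0, 1, 0 and 0, and fry gave 0, 4, 0 and 3 in the first 4. Equal cells gave 8 in pericyte-like cells, and at Leiden 0.5 the immediate early and oxidative phosphorylation lists turned downward there (2 lists). Leaving out 1 library gave 8 to 12 lists in glial-like and 6 to 15 in Wif1-led cells. The pericyte-like share reversed to -10.3 points at Leiden 0.5, and edgeR on cell numbers called the smooth muscle-like share (log2 fold -3.30) as well as the glial-like (-3.45), mesothelial-like (2.05) and unnamed (1.248) ones. In the other settings the pericyte-like, smooth muscle-like and fibroblast-like shares kept their direction, while the cardiomyocyte-like difference of -0.193 points was 0.0558 without control replicate 2.

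The replicate numbers are shared between groups without a stated pairing. As a check of pairing, deviations of same-numbered libraries correlated at 0.0864 and -0.00117 in fibroblast-like and -0.482 and -0.259 in smooth muscle-like cells. This check rests on 2 controls, whose deviations mirror each other, so it cannot tell whether libraries were paired by number. By Xist and Y-linked UMIs, both replicate 1 pools of 2 hearts held 1 female and 1 male heart. A replicate block gave 281 genes in pericyte-like, 4544 in fibroblast-like, 0 in smooth muscle-like (edgeR, 410 at an unadjusted p under 0.05) and 3517 in all cells, and 12, 10, 13 and 12 lists.

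Reversed log2 changes of named genes were, in pericyte-like cells at Leiden 0.5, Ptprz1 0.085, Elmod1 0.10, Acta2 -1.248, Vtn 0.43, Kcnj8 1.34, Abcc9 1.49, Steap4 1.06, Angpt1 0.017, Atf3 -0.98 and Ndufa4 -1.46; with the looser filter, Atf3 -0.094; and in fibroblast-like cells without the Wif1 and Chad cluster, Wif1 0.25 and Rgs5 0.94. Of the named gene and setting pairs, 1104 of pericyte-like and 1143 of fibroblast-like cells kept their direction and stayed called or stayed uncalled. A call was lost in 145 and 144 and gained in 77 and 16. In 20 and 6 the direction turned without a call in either fit, while the reversed changes above had a call in either fit. Smooth muscle-like cells could not be tested at Leiden 0.5 or with equal cells, where too few remained. The pericyte-like sum of control replicate 1 held 63612 UMIs.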

Other observations

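All tests in this part were chosen only after the results were seen. Glial-like cells, which numbered 45 and 74 in control and 27, 55 and 15 in infarct libraries, differed in 307 of 5630 genes by edgeR, of which 217 rose and 90 fell. Infarct replicate 3, with 15 cells, was under the planned minimum of 20 and was kept. Col1a1 rose from 400 ± 95.2 CPM (SD, n = 2) to 2033 ± 685 CPM (SD, n = 3), Fos from 814 ± 52.9 to 1978 ± 270 CPM and Col8a1 from 57.5 ± 46.4 to 766 ± 259 CPM. The retinaldehyde dehydrogenase gene Aldh1a1 fell from 934 ± 13.8 to 201 ± 88.2 CPM and the transporter gene Abca8b from 1251 ± 108 to 244 ± 171 CPM. Of the interstitial collagen list 13 of 20 rose (17 rose and 1 fell adjusted over the list alone; adjusted p = 8.4e-21, and adjusted p = 0.0728 with an estimated correlation), and 5 of 5 tested small leucine-rich proteoglycans rose, among them the fibroblast marker Dcn, from 45.1 to 473 CPM (adjusted p = 1.3e-09 for the list, and adjusted p = 0.194 with an estimated correlation). The immediate early and dissociation stress list, which holds Fos, had 5 of 20 that rose (12 adjusted over the list alone). Its camera adjusted p was 6.8e-08, and 0.0728 with an estimated correlation. Ribosomal protein genes had 19 of 77 that rose (62 adjusted over the list alone). Their camera adjusted p was 5.0e-23, and 0.354 with an estimated correlation. Fibroblast RNA in these droplets was not taken out. The count was 75 without control replicate 1 and 78 without control replicate 2.

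The fibroblast-like cluster led by Wif1 and Chad was compared by itself. Dcn was at 18910 ± 737 CPM in controls (SD, n = 2) and 18860 ± 2672 CPM after infarction (SD, n = 3), and Cthrc1 at 24.7 ± 3.8 and 82.2 ± 35.6 CPM (adjusted p = 0.209). The edgeR test called 0 of 13366 genes, with 827 at an unadjusted p under 0.05, while DESeq2 called 39 and limma-voom 0. By camera 11 lists passed and none with an estimated correlation, among them interstitial collagens (20 of 21 members higher, 7 rose adjusted over the list alone; adjusted p = 2.6e-11, and adjusted p = 0.273 with an estimated correlation) and matricellular proteins (12 of 14 higher, 5 rose adjusted over the list alone; adjusted p = 3.9e-09, and adjusted p = 0.273 with an estimated correlation). Leaving out control replicate 2 gave 3 and leaving out infarct replicate 2 gave 1.

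Xist, expressed from the inactive X chromosome of females, was at 309 and 474 CPM over all cells of control replicate 1 and infarct replicate 1 and at no more than 0.291 CPM in the other 3 libraries, while the Y-linked gene Ddx3y was found in all 5, from 21.8 to 120 CPM. Of the cells in control replicate 1, 46.4% had Xist and no Y-linked UMIs and 45.2% the reverse. In infarct replicate 1 the shares were 69.3% and 16.02%, and 10.97% of cells had both, against 1.21% in control replicate 1. Such cells remained after the removal of called doublets. Whether they were joined cells or held free RNA of other cells was not tested. Fibroblast-like cells made up 71.2% of the cells with Xist alone and 73.1% of those with Y-linked UMIs alone in control replicate 1, and 88.6% and 89.1% in infarct replicate 1. Pericyte-like cells made up 1.57% (6 cells) and 0.269% (1 cell) in control replicate 1, and 1.23% and 0.806% in infarct replicate 1.

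Cspg4, the gene whose promoter drives the label, was at 91.3 to 222 CPM in pericyte-like, 202 to 265 in smooth muscle-like, 60.8 to 247 in glial-like and 9.41 to 25.1 in fibroblast-like cells over the 5 libraries. Cardiomyocyte-like cells had 0 to 6 counts and mesothelial-like cells 0 to 14 counts per library. These CPM values are raw, and RNA from other cells in the same droplets was not taken out of them.

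Most sorted cells were fibroblast-like in every library, including 71.4% of control replicate 1, which argues against an entry of such cells into the fraction after infarction alone. The 24 mural markers reached at most 0.0301 of their mural level in fibroblast-like cells (median per library). These markers also named the clusters, and a cluster rich in them would not have been named fibroblast-like. The low level thus follows in part from the naming. It shows little mural RNA in the cells so named but is no separate test of mural cells joined with fibroblasts in 1 droplet. For free fibroblast RNA, the 16 fibroblast markers were at least 7.46 times higher in fibroblast-like than in glial-like and smooth muscle-like cells (median per library, lowest in infarct replicate 1; 67.5, 30.4, 18.9 and 21.5 in the others). That lowest ratio stayed under the bound of 10 for excluding free RNA. The bound was lowered to 3 once the value had been seen and then put back. It had to be passed in every library, so free RNA stays open. These 16 markers also named the fibroblast-like clusters against clusters of other classes, so a high ratio follows in part from the naming. A smooth muscle-like cluster with Dcn at 1511 CPM had 74 of its 126 cells in infarct replicate 1. Without it the ratio was 14.1 there, but leaving out cells that carry fibroblast RNA favours such a rise. It was then 225 and 134.5 in control replicates 1 and 2 and 22.55 and 21.5 in infarct replicates 2 and 3. With or without that cluster, the ratio was lower in every infarct library than in both controls, and the cause of this was not tested. The matrices hold 0 reporter features, so a label or gate that admitted cells without NG2 history could not be weighed, and whether fibroblast-like cells or their precursors expressed NG2 when tamoxifen was given is untested.

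Saa3, Hp, Cxcl5, Chl1 and Col24a1 were highest in the fibroblast-like cells of infarct replicate 3. Clusters 20, 21 and 23 together held 1.49%, 8.13% and 44.2% of the fibroblast-like cells of infarct replicates 1 to 3. These 3 clusters were picked because most of their cells came from infarct replicate 3, so their concentration there follows from that choice. The mesothelial marker Wt1 was among the leading genes of cluster 23. No other gene of the fixed mesothelial marker list was among the leading genes of the 3 clusters, and mesothelial genes outside that list were not looked for. Whether they hold cells of a mesothelial kind was not tested. Each of the 5 genes, picked as highest in infarct replicate 3, was at least 2.495 times higher there than in infarct replicate 2. Both libraries were without Xist, so the sex of the hearts cannot account for the difference between them. Infarct replicate 1, which held a female heart, was the lowest infarct library in all 5 genes, so a part of sex in its lower level stays open. The median log2 ratio of 13 macrophage markers between those 3 clusters and the other fibroblast-like cells of infarct replicate 3 was -0.085. These markers also named the clusters, and a cluster rich in them would not have been named fibroblast-like. The low ratio thus follows in part from the naming and is no separate test of doublets with macrophages. Of those markers Cd14 was higher in the clusters, at 9.39 against 2.54 CPM, as was Csf1r, at 9.11 against 4.79 CPM. Infarct replicate 3 was the 1 library from a single heart (hearts pooled: 1), and no other single-heart library can tell a difference between animals, in infarct size or position for instance, from the pooling. The pattern may therefore belong to 1 animal.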
